A study of Mus musculus with 6 samples.

How the data were processed

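Each of 6 arrays measured Cy5-labelled RNA from one sample of mouse cells, and the groups and replicate numbers were taken from the sample labels. Per the labels, 1 µg of total RNA was amplified and labelled for each array, and the lower limit on the RNA integrity number was 6. The deposited table holds probe intensity on a linear scale for 26423 probes. Some deposited values were below 0 on 4 of the 6 arrays (310, 86, 474 and 52 probes), as after background subtraction, and the sorted arrays had lower medians than the arrays of both colony groups. The background method, scanner, software and scaling are not given in the sources used here. No detection calls were used, and no genome build is named, so no positions are given.

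Probes were assigned to genes through the probe table that came with the series: 21876 carried 1 gene symbol, 0 several and 4547 none. Entrez identifiers of 21825 probes were found in the RefSeq gene table, and 0 symbols were updated. Of 19084 symbols, 2424 had several probes, and the probe with the highest mean over all arrays stood for the gene. Probes with no symbol were left out of the main tests and are counted in the closing section.

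The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The design said that deposited values would be used as they are if normalized between arrays and would otherwise be put on a log2 scale and quantile normalized, and the latter applied. Since values below 0 have no logarithm, normexp background correction with an offset of 50 (limma) was placed before the log2 step, a choice made after the values were seen. A gene was tested when at least 2 of 6 arrays lay at or above the 30th percentile of that array, which left 15459 genes. The filter's level was 7.82 on the normalized log2 scale. Intensity over background, which sets the depth of an array, is known only through this level, and the number of arrays limits the precision.

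All 6 arrays entered 1 fit in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, a mean per group, 3 residual degrees of freedom, no block). The 3 pairwise comparisons and the contrast of both colony groups with the sorted group were taken from it, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The median SE of a log2 difference was 0.134. In simulated data with the same spread, 67, 67 and 66 of 15459 genes were given 1.5-, 2- and 4-fold changes. There 2-fold changes were recovered in 82.1%, 83.6% and 71.6% of cases in the 3 pairwise comparisons. For 1.5-fold changes it was 14.9%, 10.4% and 16.4%, and for 4-fold changes 98.5% each. Calls among 15259 unchanged genes numbered 17, 16 and 8. In the data 47.1%, 15.1% and 46% of genes were called, which loosens the adjusted threshold, so these recoveries do not carry over.

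A total of 31 gene lists was written, with 889 entries, of which 809 were on the array and 726 were measured. They cover cell types (fibroblast and mesenchyme, peritubular myoid and smooth muscle, macrophage and leukocyte, endothelial, erythroid, Sertoli, Leydig, epithelial, neural, germ cell, spermatogonial, early gonad) and processes (pluripotency, HIF and oxygen sensing, hypoxia response, IGF axis, glycolysis, oxidative phosphorylation, cell cycle, immediate early, inflammation, interferon, chemokines, lysosome, cholesterol synthesis, basement membrane and integrins, Hox, imprinted, DNA methylation, Y-linked). The list on X inactivation had fewer than 5 measured members and was represented by Xist alone. The other 30 were tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the 30 lists of a comparison. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, stand beside it. Fry does not set a list against the other genes, so lists pass it readily where many genes change. The estimated form also takes its p from the 3 residual degrees of freedom, so it differs from the preset form in more than the correlation. For the fibroblast list in GSC colonies against sorted cells the estimated correlation was 0.00148, below the preset 0.01. Camera p was nonetheless 4.9e-18 with the preset and 0.00235 with the estimate. The estimate varied between lists: it was -0.0112 for Sertoli genes but 0.154 for the IGF axis, 0.137 for germ cell and 0.0789 for leukocyte genes. Where the estimate exceeded the preset, the correlation itself raised p as well. Some genes sit in several lists, such as Thy1, Dcn and Dmrt1.

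Genes were named by rule. It took, for each pairwise comparison, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, leaving out predicted-gene and clone names. To these came up to 4 members of each list, the 2 with the largest rise and the 2 with the largest fall past the threshold, and Itga6, Alpl, Igf1r, Epas1, Hif1a, Pou5f1, Cxcr4, Kit, Ddx4, Dazl, Xist and the Y-linked genes in every comparison. A subset of the genes so named is printed. Where both arrays of the lower group were under the 30th percentile of their array, the fold is a bound computed against that level, and where only the group's mean was under it, levels are given without a difference.

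Alternatives planned in advance were no normalization between arrays, median centring, no filter and a stricter filter on dim probes at the 50th percentile, the mean of a gene's probes, all probes, an intensity trend with robust variance, a fit of only the groups compared, replicate number as a block, 3 other thresholds, and leaving out each array in turn. A floor of 50 in place of normexp and a block with the GSC colony numbers exchanged were added after seeing the data. With groups of 2 arrays, no count over other splits of the arrays was made.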

Results

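Gene expression was measured on 6 single-colour (Cy5) microarrays of mouse gonadal cells, strain ICR, in 3 groups of 2 arrays. GSC colony arrays held RNA of testicular cells from 80 newborn to P2 mice that had formed colonies over 7 days in 5% O2. CD49f+ sorted arrays held RNA of cells of the same stage taken from 100 mice by magnetic sorting for CD49f, the integrin subunit encoded by Itga6, with no culture. Their labels read physiological hypoxia and give no oxygen value. PGC colony arrays held RNA of gonadal cells from 67 embryos at E11.5 that had formed colonies over 7 days in 5% O2. Per the labels, both kinds of colony were grown with laminin at 200 ng/cm2 and epidermal growth factor (EGF) at 10 ng/ml. The labels spell out GSC as glandular stem cells and PGC as primordial germ cells. The median deposited intensity was 606 and 558 on the GSC colony arrays, 393 and 406 on the sorted arrays, and 587 and 541 on the PGC colony arrays. After normalization between arrays, 15459 genes were tested. Differences between groups are on the log2 scale with their SE, and n is 2 arrays per group throughout.

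Sorted cells stood apart from both kinds of colony. Across genes, which are not independent replicates, Pearson's r between a sorted and a colony array was 0.849 to 0.880, and between a GSC colony and a PGC colony array 0.945 to 0.965. The pairs of one group reached r = 0.976 for GSC colonies, 0.990 for sorted cells and 0.989 for PGC colonies. The first principal component held 72.4% of the variance and the next one 17.7%. The difference between the arrays of a pair had an SD of 0.447 on the log2 scale for GSC colonies, 0.302 for sorted cells and 0.308 for PGC colonies. The median absolute deviation, which extreme probes move little, was 0.188, 0.186 and 0.266. On GSC colony replicate 1, 86 probes were over 4-fold higher and 179 over 4-fold lower than on replicate 2. The labels do not say whether the arrays of a group came from separate cell preparations, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

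GSC colonies were first set against CD49f+ sorted cells, which asks how testicular cells grown as colonies differ from cells of the same stage selected by their surface CD49f alone. Prl8a2 (probe PH_mM_0002295), a prolactin-family hormone gene of the decidua, was at least 139-fold higher in GSC colonies, at 14.94 ± 0.12 (SD, n = 2; limma adjusted p = 1.9e-06). Mmp3, a matrix metalloproteinase, was at least 66.3-fold higher, and Serpina3n, a serine protease inhibitor, at least 78.6-fold higher. Col6a3, a chain of collagen VI, measured 15.97 ± 0.06 in colonies and 10.14 ± 0.12 in sorted cells (SD, n = 2), a difference of 5.83 ± 0.11 (SE). In the other direction, Cst9 (probe mMC003022), a cystatin-related gene of Sertoli cells, fell by 7.88 ± 0.24 from 16.85 ± 0.05 to 8.97 ± 0.53 (adjusted p = 3.4e-06). C1qb, a complement gene of macrophages, was at least 97.3-fold lower in colonies. Fold changes are given as lower bounds wherever both arrays of the dimmer group lay under the 30th percentile of their array, since no detection calls were at hand, and levels stand without a difference where only the mean did.

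Mesenchymal genes rose together in GSC colonies. Of 31 measured fibroblast and mesenchyme genes, 28 rose and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.5e-16; adjusted p = 0.061 with an estimated correlation). Postn, which encodes the matrix protein periostin, rose by 5.77 ± 0.14, and Thy1, a surface marker shared by fibroblasts and spermatogonial stem cells, rose by 5.65 ± 0.12. Of 16 peritubular myoid and smooth muscle genes, 10 rose and 2 fell, and 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.13 with an estimated correlation). The muscle intermediate filament gene Des rose by 5.02 ± 0.15 and smooth muscle actin, Acta2, by 3.77 ± 0.10. Among 30 basement membrane and integrin genes, 19 rose and 7 fell, against 19 and 8 adjusted over the list alone (camera adjusted p = 0.0045; adjusted p = 0.34 with an estimated correlation). The laminin chain gene Lama2 rose by 4.24 ± 0.17, whereas Nid2, which encodes a nidogen, fell by 0.99 ± 0.12. The Hox list of 29 positional transcription factors had 21 members higher and 1 lower, or 22 and 1 adjusted over the list alone (camera adjusted p = 5.3e-09; adjusted p = 0.12 with an estimated correlation). Hoxa10 and Hoxa11 were at least 44.5-fold and 40.1-fold higher.

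Leukocyte, Sertoli, endothelial and erythroid markers fell in the same comparison, beside the rise of the mesenchymal lists, while the germ cell and Leydig lists did not pass. Macrophage and leukocyte genes fell in 26 of 31 cases and rose in 1, also when adjusted over the list alone (camera adjusted p = 2.3e-13; adjusted p = 0.088 with an estimated correlation). Pf4, a chemokine gene of platelets and macrophages, was at least 59.3-fold lower, and Spi1, a myeloid transcription factor, was the member that rose, by 0.93 ± 0.13. Sertoli cell genes fell in 25 of 30 cases and rose in 3, or 26 and 3 adjusted over the list alone (camera adjusted p = 5.5e-09; adjusted p = 0.061 with an estimated correlation). Amh, the anti-Müllerian hormone, was at least 25.4-fold lower, Dhh, a hedgehog ligand of Sertoli cells, fell by 3.16 ± 0.13, and the activin subunit gene Inhba rose by 3.86 ± 0.12. Endothelial genes fell in 16 of 21 cases and rose in 3, with equal counts adjusted over the list alone (camera adjusted p = 5.8e-05; adjusted p = 0.088 with an estimated correlation). Egfl7 fell by 3.84 ± 0.14, while the endothelial genes Emcn and Cd34 rose by 1.26 ± 0.11 and 1.14 ± 0.11. Of 9 erythroid genes, 8 fell, also adjusted over the list alone (camera adjusted p = 0.00038; adjusted p = 0.18 with an estimated correlation), and the globin gene Hbb-b1 was at least 6.50-fold lower. Chemokine and receptor genes fell in 12 of 22 cases and rose in 3, unchanged when adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.15 with an estimated correlation). Ccl3 was at least 83.7-fold lower and Cxcl12, the ligand of Cxcr4, rose by 2.76 ± 0.28.

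Cell cycle genes were lower in GSC colonies. Of 41 measured members, 37 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 5.1e-11; adjusted p = 0.061 with an estimated correlation). Ube2c, a ubiquitin enzyme of mitosis, fell by 2.68 ± 0.37, with an SD of 0.89 between the colony arrays. Its log2 difference was -2.0 without GSC colony replicate 1 and -3.3 without replicate 2. The members that rose were Rrm2, a subunit of ribonucleotide reductase, by 2.02 ± 0.21 and cyclin E1, Ccne1, by 1.61 ± 0.11. Immediate early and dissociation genes fell in 20 of 33 cases and rose in 4, or 21 and 4 adjusted over the list alone (camera adjusted p = 0.00068; adjusted p = 0.12 with an estimated correlation); the list's median difference of -0.59 became 0.13 without normalization between arrays, which was -0.33 relative to all genes. Fosb fell by 3.01 ± 0.26. Lysosomal genes rose in 21 of 29 cases and fell in 1, or 22 and 1 adjusted over the list alone (camera adjusted p = 2.2e-06; adjusted p = 0.080 with an estimated correlation), led by the cathepsin gene Ctsk at 5.68 ± 0.15. Interferon response genes rose in 14 of 25 cases and fell in 3, or 16 and 3 adjusted over the list alone (camera adjusted p = 0.0096; adjusted p = 0.15 with an estimated correlation), and Isg15 rose by 2.38 ± 0.12. Inflammation and wound response genes rose in 13 of 27 cases and fell in 7, or 14 and 8 adjusted over the list alone (camera adjusted p = 0.045; adjusted p = 0.34 with an estimated correlation), a call lost with either replicate block, without normalization between arrays, with median centring, with the mean of a gene's probes, in a fit of only the groups compared, and without either PGC colony array.

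Hypoxia and growth factor genes moved in both directions. Of 34 hypoxia response genes, 19 rose and 6 fell in GSC colonies, or 21 and 7 adjusted over the list alone (camera adjusted p = 0.0018; adjusted p = 0.26 with an estimated correlation). Lox, the lysyl oxidase that crosslinks collagen, rose by 5.97 ± 0.14, and by 4.76 on its other probe, whereas carbonic anhydrase Car12 fell by 2.25 ± 0.12 and the glycolysis regulator Pfkfb3 by 1.78 ± 0.12. IGF axis genes rose in 13 of 26 cases and fell in 5, or 14 and 6 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.45 with an estimated correlation). The binding protein genes Igfbp6 and Igfbp5 rose by 5.52 ± 0.15 and 4.94 ± 0.14, and Irs2, an insulin receptor substrate, fell by 2.06 ± 0.13.

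The 10 genes that the study's topic names were followed whatever their values. Epas1, which encodes HIF-2α, measured 14.43 ± 0.05 in GSC colonies and 13.05 ± 0.19 in sorted cells (SD, n = 2; limma adjusted p = 0.0016), a rise of 1.38 ± 0.20, while its other probe differed by 0.48 (adjusted p = 0.33). Pou5f1, the gene of OCT4, rose by 0.92 ± 0.11 (adjusted p = 0.00066) and the germ cell RNA-binding gene Dazl by 1.45 ± 0.18 (adjusted p = 0.00089). Alpl, the alkaline phosphatase gene, fell by 2.52 ± 0.17 (adjusted p = 5.9e-05) and Kit, a receptor tyrosine kinase, by 1.14 ± 0.16 (adjusted p = 0.0016). Cxcr4, a chemokine receptor, was at least 1.67-fold lower (adjusted p = 0.00082). Ddx4, a germ cell helicase, differed by 0.26 ± 0.13 and did not pass (adjusted p = 0.17). Hif1a rose by 0.48 ± 0.16 (adjusted p = 0.047), a call lost in several other settings. Itga6 fell by 0.37 ± 0.12 and Igf1r by 0.37 ± 0.12 (adjusted p = 0.042 and 0.046), and without normalization between arrays these differences were 0.20 and 0.22. Xist, the RNA of the inactive X chromosome, lay near the filter's level at 7.81 ± 0.08 in GSC colonies and 8.16 ± 0.06 in sorted cells (SD, n = 2; limma adjusted p = 0.043), a call lost without normalization between arrays. None of the 5 measured Y-linked genes passed limma's test, adjusted or unadjusted (camera adjusted p = 0.54), with Eif2s3y at 0.06 ± 0.17 and Uty at -0.27 ± 0.12.

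For 14 lists camera did not pass in this comparison. Germ cell genes came closest, with 8 of 25 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.079); Taf7l, a germ cell transcription factor subunit, rose by 2.13 ± 0.15 and the Sertoli and germ cell gene Dmrt1 fell by 2.94 ± 0.21. Among 30 spermatogonial stem and progenitor genes 7 rose and 11 fell (7 and 12 adjusted over the list alone; camera adjusted p = 0.54), among 18 pluripotency genes 5 rose and 3 fell (camera adjusted p = 0.37), and among 25 early gonad genes 12 rose and 11 fell (12 and 12 adjusted over the list alone; camera adjusted p = 0.60), a list whose median, mean and test differed in sign. Imprinted genes rose in 13 of 30 cases and fell in 8, or 13 and 9 adjusted over the list alone (camera adjusted p = 0.37). HIF and oxygen sensing genes rose in 3 of 12 cases and fell in 5, and glycolysis genes rose in 7 of 16 and fell in 4 (camera adjusted p = 0.54 for both). Oxidative phosphorylation genes rose in 3 of 40 cases and fell in 10, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.55). DNA methylation genes rose in 4 of 15 cases and fell in 7, and neural genes rose in 6 of 16 and fell in 3 (camera adjusted p = 0.37 for both). Cholesterol synthesis genes rose in 5 of 20 cases and fell in 4 (camera adjusted p = 0.75), epithelial genes rose in 7 of 25 and fell in 10 (7 and 12 adjusted over the list alone; camera adjusted p = 0.38), and Leydig cell genes rose in 4 of 11 and fell in 5 (camera adjusted p = 0.42). Where no separate counts are given for these lists, those adjusted over the list alone were equal.

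In all, 7279 of 15459 genes, 47.1%, changed between GSC colonies and sorted cells at limma adjusted p under 0.05, of which 3486 were higher and 3793 lower in colonies and 3204 differed at least 2-fold. Camera with its preset correlation passed 16 of 30 lists, 9 up and 7 down, and fry passed 27. Fry's count does not speak for a shift beyond that of other genes. The oxidative phosphorylation list passed it (fry adjusted p = 0.0035) with 27 of 40 members not past limma's test. With an estimated correlation, which also rests on 3 residual degrees of freedom, camera passed 0 at an adjusted p under 0.05 and 10 at an unadjusted one. Without normalization between arrays the list calls for the IGF axis and interferon were also lost, the median gene shifted by 0.465, and 8179 genes were higher and 1732 lower. Culture, with its laminin and EGF, and selection by CD49f differ together between these groups, so neither can be set apart. The oxygen around the sorted cells is labelled only as physiological hypoxia, so whether it differs from the 5% O2 of the colonies is not known.

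**Figure D1:**
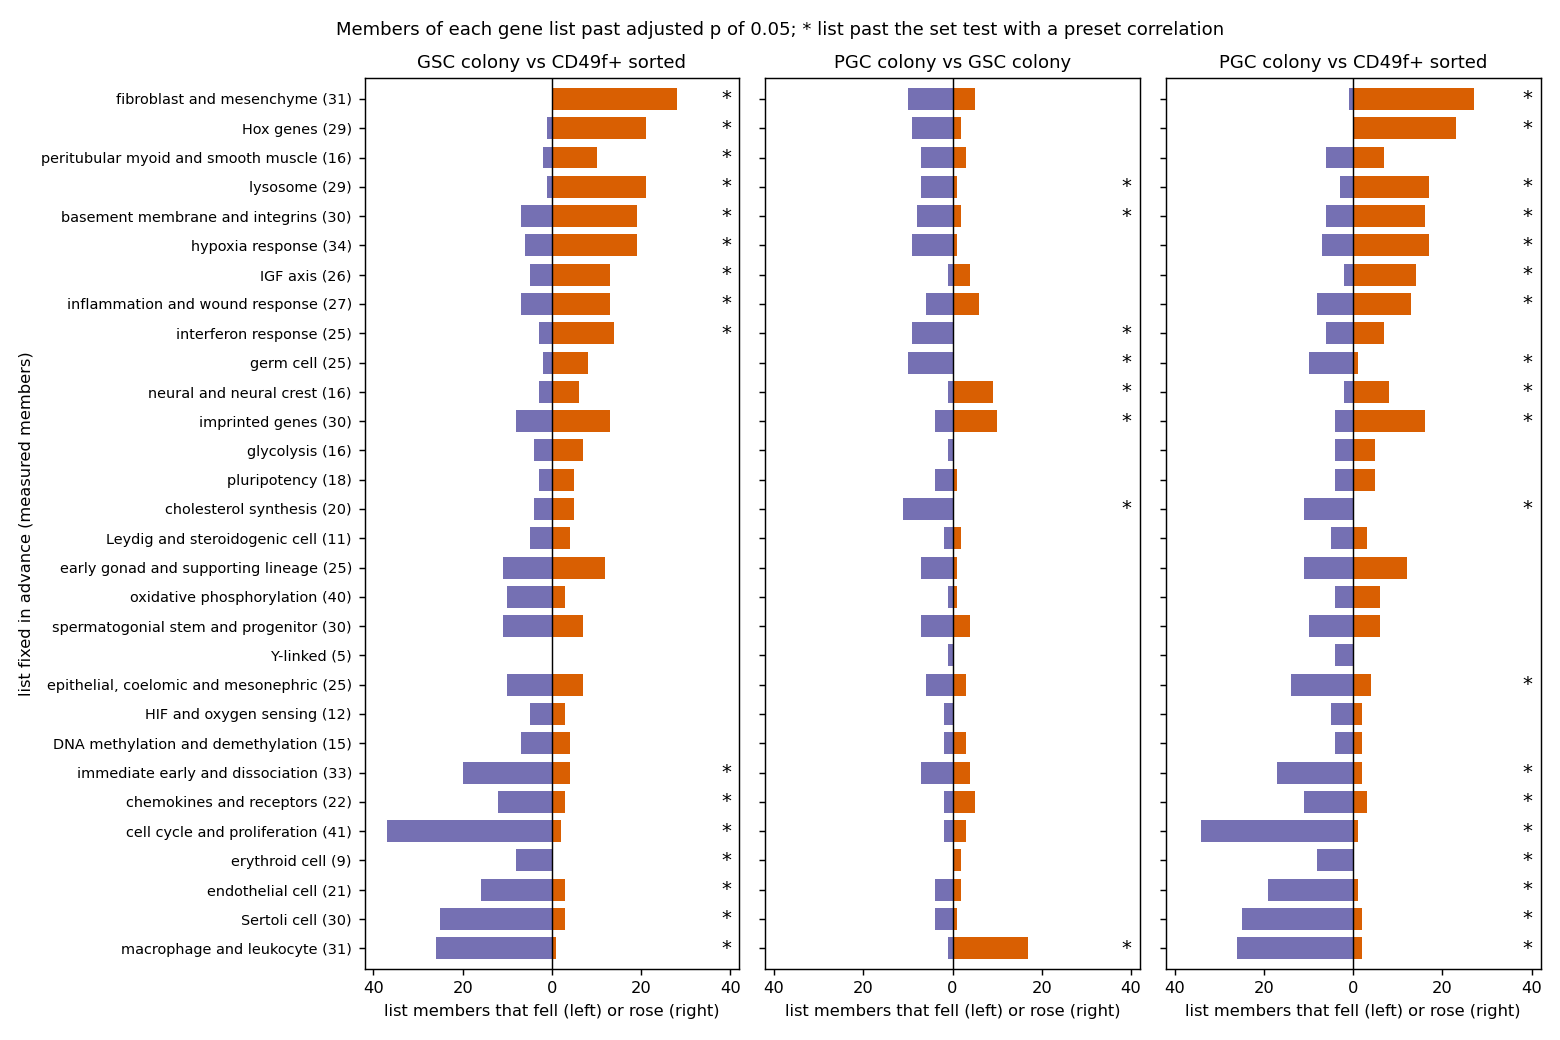
Number of measured members of each fixed gene list that rose (right of 0) or fell (left of 0) at limma adjusted p under 0.05, one panel per pairwise comparison, with an asterisk where camera with its preset correlation passed. Of 31 fibroblast genes 28 rose in GSC colonies and 27 in PGC colonies against sorted cells, and imprinted genes, past camera in PGC against GSC colonies, had a median of 0.03 that became -0.04 without normalization between arrays.

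PGC colonies were then compared with GSC colonies, both grown under the same conditions, which asks how cells of the embryonic gonad and of the postnatal testis differ after colony formation. Testicular cells are male, whereas the sex of the embryos is not given in the labels used here, so sex may differ too. Meox2 (probe mMC013934), a homeobox gene of the early muscle lineage, was higher in PGC colonies, at 13.17 ± 0.01 against 7.73 ± 0.25 in GSC colonies (SD, n = 2; limma adjusted p = 1.9e-05). The imprinted genes Mest and Igf2 rose by 5.34 ± 0.12 and 3.95 ± 0.11, and Igf2, a growth factor gene, reached 17.64 ± 0.04 (SD, n = 2). Striated muscle genes were among the 10 with the largest rise: the embryonic myosin gene Myh3 rose by 3.96 ± 0.29, the skeletal actin gene Acta1 was at least 9.01-fold higher, and the cardiac actin gene Actc1 measured 11.92 ± 0.12 against 7.56 ± 1.00 (SD, n = 2; adjusted p = 0.0027). In the other direction, Prl8a2 was at least 140-fold lower in PGC colonies and the proteoglycan gene Srgn (probe PH_mM_0008293) at least 131-fold lower (adjusted p = 4.8e-06 for both). Gpx3, a glutathione peroxidase, fell by 5.51 ± 0.10, from 17.20 ± 0.03 to 11.69 ± 0.06 (SD, n = 2).

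Epas1 was lower in PGC colonies, at 10.63 ± 0.37 against 14.43 ± 0.05 (SD, n = 2), and fell by 3.80 ± 0.20 (adjusted p = 0.00013), while its other probe differed by -0.72 (adjusted p = 0.26). Pou5f1 fell by 1.13 ± 0.11 (adjusted p = 0.0012), and Dazl was at least 4.87-fold lower (adjusted p = 0.00034). Itga6 rose by 0.58 ± 0.12 (adjusted p = 0.023), a call lost in 4 other settings, the replicate block among them. Kit, Igf1r, Alpl, Ddx4 and Hif1a did not pass, with differences of 0.19 ± 0.16, -0.17 ± 0.12, -0.29 ± 0.17, -0.41 ± 0.13 and -0.52 ± 0.16 (adjusted p = 0.49, 0.41, 0.30, 0.096 and 0.077). Cxcr4 lay under the 30th percentile on all arrays of both groups, and no fold is given (adjusted p = 0.10). Xist was higher, at 8.80 ± 0.06 against 7.81 ± 0.08 (SD, n = 2; limma adjusted p = 0.0024), and of the 5 Y-linked genes Eif2s3y fell by 0.89 ± 0.17 (adjusted p = 0.017), whereas Uba1y, Kdm5d, Usp9y and Uty did not pass, at -0.05, -0.24, -0.29 and -0.43 (camera adjusted p = 0.072), and adjusted over the list alone 2 of the 5 fell.

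Germ cell genes fell in PGC colonies relative to GSC colonies in 10 of 25 cases, or 15 adjusted over the list alone, and the others did not pass (camera adjusted p = 1.4e-07; adjusted p = 0.27 with an estimated correlation). Mael, a gene of the piRNA pathway, fell by 2.04 ± 0.11. Macrophage and leukocyte genes rose in 17 of 31 cases and fell in 1, or 18 and 1 adjusted over the list alone (camera adjusted p = 1.3e-08; adjusted p = 0.20 with an estimated correlation). Tyrobp, an adaptor of myeloid receptors, was at least 3.60-fold higher, and Cd14, a myeloid surface receptor gene, was the member that fell, by 1.18 ± 0.11. Of 52 other leukocyte genes 7 rose and 2 fell, with a median log2 difference of 0.13 (camera p = 0.049; p = 0.137 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 20 cases, and adjusted over the list alone 12 fell and 1 rose (camera adjusted p = 1.5e-05; adjusted p = 0.19 with an estimated correlation). Idi1 fell by 1.77 ± 0.11 and Msmo1 by 1.33 ± 0.11, both enzymes of that pathway. Interferon response genes fell in 9 of 25 cases, or 12 adjusted over the list alone (camera adjusted p = 4.5e-05; adjusted p = 0.19 with an estimated correlation), and Ifi27l2a fell by 1.98 ± 0.11. Neural and neural crest genes rose in 9 of 16 cases and fell in 1, or 11 and 1 adjusted over the list alone (camera adjusted p = 8.4e-05; adjusted p = 0.19 with an estimated correlation). The axon growth genes Gap43 and Stmn2 rose by 2.70 ± 0.14 and 1.36 ± 0.12.

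Lysosomal genes fell in 7 of 29 cases and rose in 1, with equal counts adjusted over the list alone (camera adjusted p = 0.0046; adjusted p = 0.20 with an estimated correlation), and Ctsk fell by 3.26 ± 0.15. Basement membrane and integrin genes fell in 8 of 30 cases and rose in 2, or 9 and 2 adjusted over the list alone (camera adjusted p = 0.021; adjusted p = 0.38 with an estimated correlation); the laminin gene Lama5 fell by 1.27 ± 0.14. Imprinted genes rose in 10 of 30 cases and fell in 4, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.047; adjusted p = 0.33 with an estimated correlation), and the list's median of 0.03 became -0.04 without normalization between arrays and -0.02 with median centring. Tfpi2, an imprinted gene of a protease inhibitor, fell by 3.30 ± 0.21. Among lists that did not pass camera, fibroblast genes rose in 5 of 31 cases and fell in 10 (6 and 12 adjusted over the list alone; camera adjusted p = 0.086), and Postn fell by 2.16 ± 0.14. Hox genes rose in 2 of 29 cases and fell in 9, or 6 and 11 adjusted over the list alone (camera adjusted p = 0.086), and Hoxa11 fell by 3.41 ± 0.12. Hypoxia response genes rose in 1 of 34 cases and fell in 9, or 3 and 9 adjusted over the list alone (camera adjusted p = 0.081), and Lox fell by 3.98 ± 0.14. Cell cycle genes rose in 3 of 41 cases and fell in 2, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.57). Median, mean and test differed in sign for the glycolysis, HIF, immediate early, inflammation, Leydig and spermatogonial lists, none of which passed camera.

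Between the colony groups 2329 of 15459 genes, 15.1%, changed at limma adjusted p under 0.05, 1095 higher and 1234 lower in PGC colonies, and 799 differed at least 2-fold. Of these 799, 312 were higher and 487 lower. Without normalization between arrays 921 genes were higher and 1405 lower, so the split depends on the threshold and on that step. Camera with its preset correlation passed 8 of 30 lists, 3 up and 5 down, an estimated correlation 0 at an adjusted p under 0.05 and 5 at an unadjusted one, and fry 25. In a fit of only the 2 colony groups 1601 genes were called. The count therefore leans on the sorted arrays, which enter the shared estimate of spread. The imprinted list's call was lost without normalization between arrays, with median centring, with either replicate block, with the floor, with the mean of a gene's probes and without either PGC colony array, and the basement membrane call with the stricter filter and without PGC colony replicate 2.

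**Figure D2:**
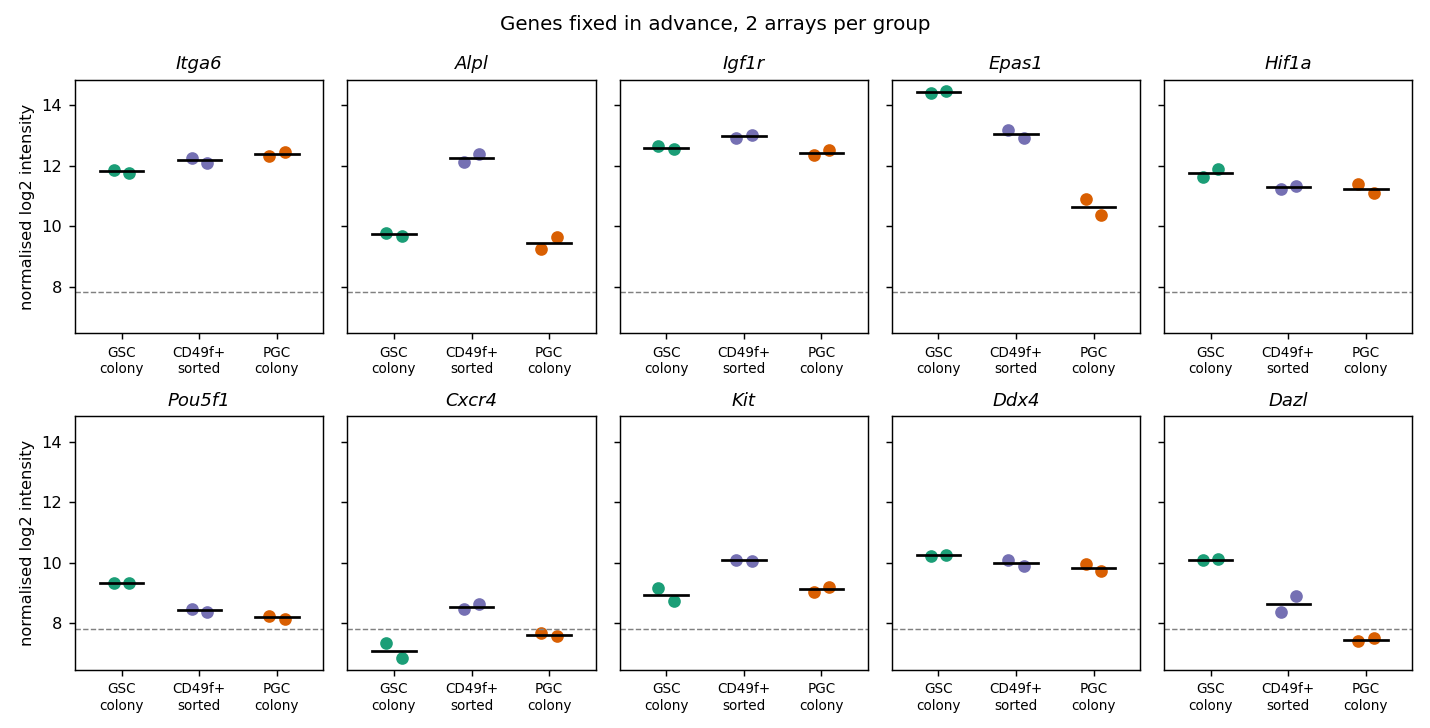
Normalized log2 intensity of the 10 genes that the study's topic names, with a point per array in each of the 3 groups, a bar at the group mean and a dashed line at the mean 30th-percentile level of the arrays. Epas1 has group means of 14.43 in GSC colonies, 13.05 in sorted cells and 10.63 in PGC colonies, and Itga6 and Igf1r, whose differences between GSC colonies and sorted cells turn sign without normalization between arrays, vary by less than 1 between groups.

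PGC colonies were last set against CD49f+ sorted cells, a comparison in which stage, tissue, culture and selection by CD49f differ at once. Sex and surrounding oxygen may differ too, as neither the sex of the embryos nor an oxygen value for the sorted cells is given. Prkg2, a cGMP-dependent protein kinase, was at least 55.3-fold higher in PGC colonies (limma adjusted p = 3.9e-06). Ccn4, a secreted matricellular gene, rose by 6.30 ± 0.10 to 14.29 ± 0.04 (SD, n = 2), and Pdgfrb, a growth factor receptor of mesenchymal cells, by 6.21 ± 0.11. Trib3, a pseudokinase of the amino acid stress response, rose by 5.72 ± 0.12. In the other direction, Cst12 (probe PH_mM_0009329), a cystatin-family gene, fell by 8.58 ± 0.12, from 16.98 ± 0.05 to 8.40 ± 0.13 (SD, n = 2; adjusted p = 3.2e-06). Lyve1, a receptor of lymphatic endothelium and macrophages, was at least 55.7-fold lower.

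Fibroblast genes rose in PGC colonies in 27 of 31 cases and fell in 1, with equal counts adjusted over the list alone (camera adjusted p = 8.5e-15; adjusted p = 0.052 with an estimated correlation), with fibronectin, Fn1, at 5.75 ± 0.14. Hox genes rose in 23 of 29 cases and the others did not pass, also adjusted over the list alone (camera adjusted p = 1.0e-09; adjusted p = 0.11 with an estimated correlation), and Hoxc6 rose by 3.94 ± 0.15. Lysosomal genes rose in 17 of 29 cases and fell in 3 (camera adjusted p = 0.00093; adjusted p = 0.11 with an estimated correlation), with equal counts adjusted over the list alone. IGF axis genes rose in 14 of 26 cases and fell in 2, or 15 and 3 adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.33 with an estimated correlation), and Igfbp5 rose by 5.30 ± 0.14. Imprinted genes rose in 16 of 30 cases and fell in 4, or 16 and 6 adjusted over the list alone (camera adjusted p = 0.0096; adjusted p = 0.14 with an estimated correlation). The imprinted genes Dlk1 and H19 rose by 4.58 ± 0.14 and 3.83 ± 0.12. Neural genes rose in 8 of 16 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.014; adjusted p = 0.14 with an estimated correlation), and the neurofilament gene Nefm rose by 3.58 ± 0.21. Hypoxia response genes rose in 17 of 34 cases and fell in 7, or 18 and 8 adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.33 with an estimated correlation). Basement membrane genes rose in 16 of 30 cases and fell in 6, or 16 and 9 adjusted over the list alone (camera adjusted p = 0.036; adjusted p = 0.38 with an estimated correlation). Inflammation genes rose in 13 of 27 cases and fell in 8, or 15 and 8 adjusted over the list alone (camera adjusted p = 0.040; adjusted p = 0.33 with an estimated correlation), a call lost with median centring, with the crossed replicate block and without PGC colony replicate 2.

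Several lists of cell type markers fell in PGC colonies, unlike the fibroblast and neural lists. Macrophage and leukocyte genes fell in 26 of 31 cases and rose in 2, also adjusted over the list alone (camera adjusted p = 3.5e-11; adjusted p = 0.11 with an estimated correlation), and C1qa fell by 5.31 ± 0.49. Sertoli cell genes fell in 25 of 30 cases and rose in 2, with equal counts adjusted over the list alone (camera adjusted p = 4.5e-10; adjusted p = 0.052 with an estimated correlation), and Cst9 fell by 6.74 ± 0.24. Endothelial genes fell in 19 of 21 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 1.0e-08; adjusted p = 0.054 with an estimated correlation), and the endothelial cadherin gene Cdh5 fell by 3.35 ± 0.10. Erythroid genes fell in 8 of 9 cases, also adjusted over the list alone (camera adjusted p = 0.00093; adjusted p = 0.17 with an estimated correlation). Chemokine genes fell in 11 of 22 cases and rose in 3, or 12 and 3 adjusted over the list alone (camera adjusted p = 0.0053; adjusted p = 0.14 with an estimated correlation), and Ccl3 fell by 5.35 ± 0.13. Epithelial genes fell in 14 of 25 cases and rose in 4, also adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.14 with an estimated correlation), and their median of -0.42 became 0.01 without normalization between arrays, -0.41 relative to all genes. Krt8, a keratin of simple epithelia, fell by 3.35 ± 0.48.

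Cell cycle genes fell in 34 of 41 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 3.5e-11; adjusted p = 0.052 with an estimated correlation). Kif23, a mitotic kinesin, fell by 2.64 ± 0.14, and Ccne1 was the member that rose, by 1.67 ± 0.11. Immediate early genes fell in 17 of 33 cases and rose in 2, or 17 and 3 adjusted over the list alone (camera adjusted p = 0.0019; adjusted p = 0.14 with an estimated correlation), and their median of -0.45 became 0.07 without normalization between arrays, -0.35 relative to all genes. Cholesterol synthesis genes fell in 11 of 20 cases, and adjusted over the list alone 11 fell and 1 rose (camera adjusted p = 0.013; adjusted p = 0.14 with an estimated correlation). Germ cell genes fell in 10 of 25 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 0.020; adjusted p = 0.38 with an estimated correlation), and their median of -0.33 became 0.14 without normalization between arrays, -0.29 relative to all genes. Dazl was at least 1.78-fold lower (adjusted p = 0.0022) and Cxcr4 at least 1.67-fold lower (adjusted p = 0.0060). Epas1 fell by 2.42 ± 0.20 (adjusted p = 0.00015), with -0.23 on its other probe (adjusted p = 0.66). Alpl fell by 2.81 ± 0.17, Kit by 0.95 ± 0.16 and Igf1r by 0.54 ± 0.12, and the Igf1r call was lost without normalization between arrays. Pou5f1, Ddx4, Hif1a and Itga6 did not pass, at -0.22 ± 0.11, -0.16 ± 0.13, -0.05 ± 0.16 and 0.21 ± 0.12. Xist rose by 0.64 ± 0.11, and the Y-linked genes Eif2s3y, Uty, Usp9y and Kdm5d fell by 0.83, 0.71, 0.47 and 0.41; without normalization between arrays none of these 4 calls held and the Kdm5d difference was 0.02.

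Between PGC colonies and sorted cells 7111 of 15459 genes, 46.0%, changed at limma adjusted p under 0.05, 3517 higher and 3594 lower, and 3085 differed at least 2-fold. Without normalization between arrays 7574 were higher and 1838 lower, so the even split depends on that step. Camera with its preset correlation passed 19 of 30 lists, 9 up and 10 down, an estimated correlation 0 at an adjusted p under 0.05 and 9 at an unadjusted one, and fry 28. Without normalization between arrays 13 lists passed, and the calls for basement membrane, germ cell, hypoxia, imprinted, inflammation and neural genes were lost, as was the germ cell call without PGC colony replicate 2 and the neural call with the stricter filter. Median, mean and test differed in sign for the early gonad, oxidative phosphorylation and pluripotency lists, none of which passed.

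The mean of both colony groups differed from the sorted cells in 7812 genes, 3863 higher and 3949 lower, against 8794 and 1886 without normalization between arrays. Of the genes called in each separate comparison with the sorted cells, 2633 were higher in both, 2926 lower in both and 133 moved in opposite directions. Lists drawn independently would share 793 and 882. As both comparisons use the same sorted arrays, their differences correlate across genes even without any change: r was 0.852, against 0.503 in 20 simulations with no change. There limma called 0 genes in both comparisons, but a simulation without changed genes leaves almost none to call. A gene that differs only in the sorted cells can be called in both comparisons. Neither this 0 nor the values for independent lists is therefore a baseline for the shared calls.

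**Figure D3:**
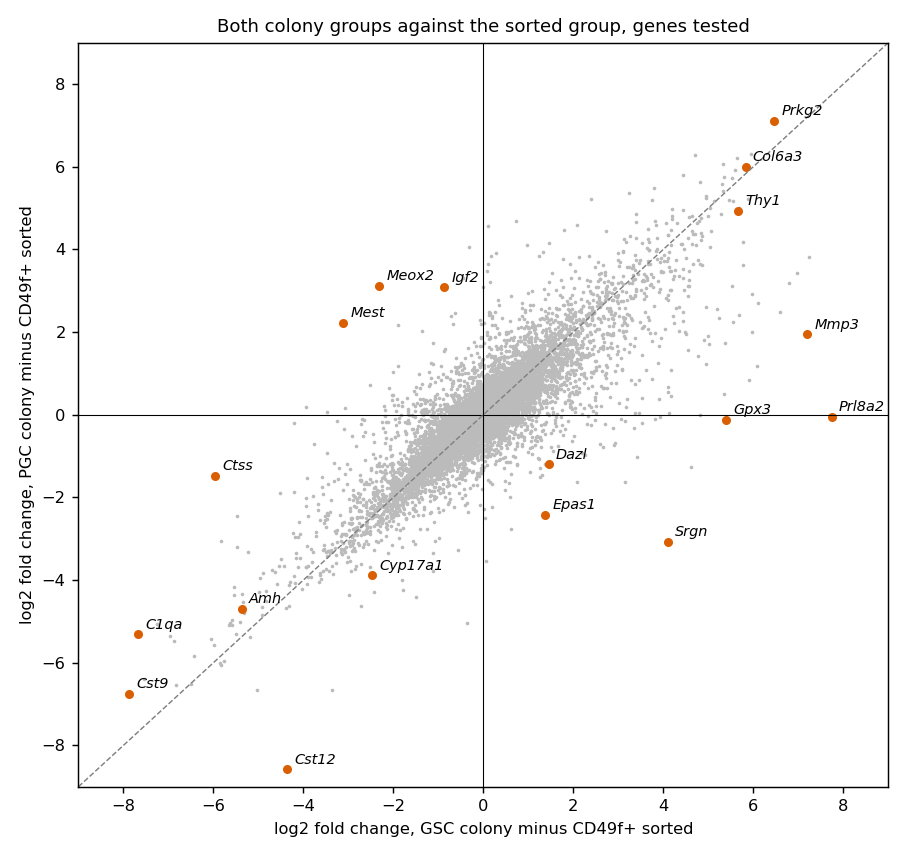
Log2 difference of each of 15459 genes between GSC colonies and sorted cells (horizontal axis) and between PGC colonies and sorted cells (vertical axis), with named genes labelled and a dashed line where both are equal. Col6a3 lies near that line at 5.83 and 6.00, and Prl8a2 far to its right.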

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

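Of the tests in this part, that on a smaller mesenchymal share was chosen after the result was seen, and that on leukocytes after the pattern but before the values of its genes were seen. Probes with no gene symbol lie outside the comparisons by gene, and 2295 of them passed the filter on dim probes. Tested in the same way with limma, 565 of them changed between GSC colonies and sorted cells (242 higher, 323 lower), 175 between PGC and GSC colonies (97 higher, 78 lower) and 561 between PGC colonies and sorted cells (260 higher, 301 lower).

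The first pattern weighed is a set of 178 probes past the filter on dim probes that lay over 4-fold lower on GSC colony replicate 1 than on replicate 2, with a median log2 difference of -2.89. If the RNA of these genes differed between the arrays, other probes of the same genes would differ too. For 37 other probes of 31 of these genes the median difference was -0.0174. Defects of single probes on that array are a candidate explanation that met this test, and a difference in RNA is argued against for the genes that have another probe. No biological explanation was tested, and genes with 1 probe stay open.

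A further 254 probes rose together on GSC colony replicate 1, sorted replicate 2 and PGC colony replicate 2, by a median of 1.09, whereas other arrangements of the replicates gave 15, 7 and 11 probes in all. The median shift of 32 other probes of the same genes was -0.0411. An effect on single probes rather than on the RNA of their genes may therefore account for the pattern, and what produced it stays open. The arrangement runs across the replicate numbers, so it adds to the spread within each group and not to a difference between groups.

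Leukocyte and endothelial markers were higher in the sorted group than in GSC colonies. Leukocytes among the sorted cells are a candidate source of the leukocyte markers. Of 52 measured leukocyte genes outside the fixed list, 39 were higher in the sorted group and 1 lower (camera p = 1.84e-12, and p = 0.00549 with an estimated correlation). Among all 15459 genes tested, 3793 were higher in the sorted group and 3486 lower. C1qa and Pf4 of the fixed list reached 15.08 and 13.71 on the log2 scale. Sorting for CD49f need not remove leukocytes, as some leukocytes and platelets carry it. The source of the endothelial markers was not tested. A smaller share of mesenchymal cells that raises the markers of every other cell type alike was also weighed. The mean difference of the leukocyte list minus that of the germ cell list was -3.61 (permutation p = 1e-05, the smallest that 100000 permutations can give). As these lists were picked after they were seen to part, this p cannot count as support. List means were -3.37 for leukocyte, -2.02 for Sertoli, -1.645 for endothelial and -1.6 for erythroid genes, against -0.46 for Leydig and 0.24 for germ cell genes. The Leydig list was mixed, with 4 of 11 members higher and 5 lower. Its members Hsd17b3 and Cyp17a1 fell by 2.71 and 2.47, while Thbs2 was at least 10.6-fold higher and Cyp11b1 rose by 0.94. Dazl of the germ cell list, which rose, lay at only 8.65 in sorted cells, which left little room for a fall. The list means did not fall alike, but list make-up and low signal may contribute. They therefore do not decide the question, and a smaller mesenchymal share stays open. Loss of leukocytes over 7 days of culture, with equal numbers at the start, was not tested and stays open, as does the biological difference between colonies and sorted cells that the design names.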

How the results depend on the processing

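The floor in place of normexp and the crossed replicate block were chosen after seeing the data. Comparisons follow the order GSC colonies against sorted cells, PGC against GSC colonies, PGC colonies against sorted cells, and both colony groups against sorted cells. Counts of genes moved most with the threshold: 3204, 799, 3085 and 3038 at 2-fold with an adjusted p, 3231, 855, 3111 and 3054 at 2-fold with an unadjusted p, and 3076, 552, 2968 and 3141 when tested against a 1.5-fold change. The criterion with an unadjusted p changes 2 choices at once, and 3204, 799, 3085 and 3038 of its genes were also called by the main criterion. With the replicate block the counts were 6804, 1707, 6637 and 7306, with the crossed block 7831, 2703, 7672 and 8363, and with the floor 7176, 2238, 7023 and 7715. Leaving out 1 array gave 5433 to 7775, 1484 to 2095, 5279 to 7052 and 5709 to 7931, the lone array of a group being assumed to vary like the other groups; 1484 was without GSC colony replicate 1. Without normalization between arrays the counts were 9911, 2326, 9412 and 10680, of which 82.5%, 80.5% and 82.3% were higher in colonies in the 3 comparisons with sorted cells, and the median gene shifted by 0.465, -0.031, 0.423 and 0.447, so the balance of higher and lower genes there rests on the normalization. That setting also turned 8 named differences: in GSC colonies against sorted cells Xist to 0.003, Itga6 to 0.201, Igf1r to 0.224, Arnt to 0.091, Ndufb8 to 0.11 and Ndufa4 to 0.093, and in PGC colonies against sorted cells Kdm5d to 0.017 and Atp5e to 0.131. Under 16 alternatives 112 of 133, 92 of 120 and 113 of 132 named genes kept their direction and their side of the threshold. The naming rule takes the largest changes, which favours such stability, and the other thresholds and the all-probe setting are not among the 16. Over all genes, 6708 of 7279, 1689 of 2329 and 6560 of 7111 calls in the pairwise comparisons were also made with the replicate block. The stricter filter left some named genes untested, and these count as kept in that setting. For gene lists, camera with an estimated correlation passed 0, 0 and 0 at an adjusted p under 0.05 (10, 5 and 9 at an unadjusted one) and fry 27, 25 and 28, and leaving out 1 array gave 15 to 16, 6 to 12 and 17 to 19. Camera with an estimated correlation also changes its degrees of freedom, so its calls are not set by the correlation alone. Except where the construction is named, the cause was not tested. Genes near background are limited by their signal: where both arrays of the lower group lie under the filter's level a fold is only a bound.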

Other observations

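Both tests in this part use lists written after some of their genes had been seen in the data, and those genes were left out of the counts; the tests on the remaining members were set before their values were seen. Genes of the amino acid response driven by the transcription factor ATF4 were higher in colonies. Of 31 measured members not seen before, 26 were higher in the mean of both colony groups than in the sorted cells, with a median difference of 1.60 (camera p = 1.45e-12, and p = 0.00397 with an estimated correlation). In GSC colonies 25 of the 31 rose and in PGC colonies 26, while 5 were higher in PGC than in GSC colonies. Slc7a3, a transporter of cationic amino acids, was higher than in sorted cells by 4.43 in GSC colonies and 4.95 in PGC colonies, Atf5 by 3.87 and 4.28, and Ddit3, a stress-induced transcription factor, by 3.24 and 3.58. Of all 15459 genes tested, 3863 were higher in the same contrast. An ATF4 amino acid response in both colony groups may account for the rise of Trib3, Chac1, Nupr1 and Aldh1l2 as well, since 26 of the 31 members met the test. The list cannot tell such a response from another stress that moves the same genes. Whether the medium, the oxygen or the cell types bring the rise cannot be set apart with these groups.

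Some genes of skeletal muscle were higher in PGC colonies than in GSC colonies. Of 33 measured members not seen before, 16 rose and the others did not pass (camera p = 8.46e-07, and p = 0.0532 with an estimated correlation). Among all 15459 genes tested, 1095 were higher in this comparison. Tnnc2, a fast troponin, was higher by 2.15 and Myog, a transcription factor of muscle differentiation, by 1.84. Skeletal muscle cells or a muscle programme in the PGC colonies are a possible explanation that 16 of 33 members leave open, as the test asked for a larger share.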
